A study of Homo sapiens with 2 samples.

How the data were processed

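Total RNA of H460 cells was made into libraries with the Illumina TruSeq RNA kit, per the labels' protocols, and 1 library each was sequenced from vector cells and from cells overexpressing PKP2. The submitters' processing notes name Bowtie 0.12.2 and the human builds GRCh37 and hg19. The program that counted reads, its gene annotation, its use of strand and its treatment of reads shared between genes are not given in the sources used here. Overlapping genes, antisense pairs and near-identical copies may therefore have had their reads split in a way that cannot be checked.

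The deposited values are counts per Ensembl gene ID, not normalized, per the file headers, and were whole numbers except in 1 damaged row. They are classed as estimated counts, not normalized as deposited, because of the decimal in that row alone. No rounding was needed. In each file 2 rows were left out: the row of TGFB1, which has no value, and a row with a text fragment and a decimal number. TGFB1 was not analysed here, and since these rows hold no readable gene count their share of the counts cannot be given. The files list 22965 gene IDs, and no gene at 0 in both libraries is listed. Symbols were found for 22579 IDs in a table of gene names.

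Library sizes were the totals over all listed genes times edgeR's TMM factors (1.01 for vector, 0.991 for PKP2; edgeR 4.0.16, R 4.3.3), used for scaling only. The log2 ratio of each gene was that of its CPM (its count over the scaled library size, times a constant), with no pseudocount, and its 95% interval was an exact binomial (Clopper-Pearson) interval of the 2 counts. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A gene at 0 in a library was set against a floor of 3 counts, which is 0.126 CPM in the vector and 0.149 CPM in the PKP2 library. With 1 library per group, edgeR's quasi-likelihood test cannot estimate the spread between cultures, so no p-value was computed. Genes with a mean of at least 10 counts were described as at least 2-fold higher, at least 2-fold lower or within 2-fold. For each of 35 gene lists the median ratio was given with a 95% order-statistic interval over members (for at least 6 members) and its percentile among 10000 random lists of the same size, drawn within 20 bins of mean expression.

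The lists, the 2-fold threshold and the rule for named genes were fixed before the data were examined. The rule named PKP2, the 12 highest and 12 lowest ratios with 1 CPM added, up to 4 measured members per list with the ratios farthest from 0, and CTNNB1, LIG4 and EGFR, 153 genes in all. A few genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen. Alternatives fixed at the same time were pseudocounts of 0.1, 0.5 and 5 CPM, no filter or a mean of at least 50 counts, other scalings, thresholds of 1.5-fold and 3-fold, means of lists and unmatched random lists. DESeq2 1.42.0 size factors, a pseudocount of 1 CPM, corrections for GC content and transcript length, and a restriction to genes with few shared sequences were added after the data were seen.

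Transcript GC content, length, gene type, exon overlaps and shared sequences came from GENCODE release 29. Its build is not the one named in the processing notes, so it was used by gene ID and for neighbouring genes, with no coordinates. Of the genes with a mean of at least 10 counts, 99.4% had a transcript. GC content and length were those of the APPRIS principal transcript where one is marked and otherwise of the longest. They were first taken from the longest transcript of every gene and redefined after those results were seen, and both sets are reported. A lowess curve (fraction 0.3; statsmodels 0.14.6) over genes with a mean of at least 100 counts was subtracted for each correction, or the median of the 100 nearest such genes in GC content and log2 length. Members of the ribosomal protein, nuclear respiratory chain and ATF4 lists were left out of these nearest genes for every list. Shared sequence was the percentage of a gene's 31-base stretches (31-mers), over all its transcripts and on either strand, found in another listed gene. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

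The steps were tested on simulated counts with the means and sizes of these libraries, for the PKP2 library against the vector library over 15991 genes at or above the count minimum. Of 200 genes given a change, 196 were among them. Of genes made 3-fold higher 98% were found at least 2-fold higher, of genes made 3-fold lower 95.7%, and of those made 6-fold higher or lower 100%. The counting interval held the true ratio for 95.6% of unchanged genes. Of 100 random unchanged lists 96% lay within the middle 95% of their random lists, and of 100 lists shifted by -0.3 100% lay under the 2.5th percentile. The shifted lists were drawn only from the upper bins of mean expression, so shifts in lists with members of few counts may be found less often. The simulation holds counting error only, not the variation between cultures. Its unchanged genes also have no trend with GC content and no other spread between genes. Shifted lists may therefore be found less often in these libraries than in the simulation.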

Results

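RNA-seq gene counts were compared between 2 libraries of H460 cells, a human large-cell lung cancer line. The first came from cells carrying the pSin-puro vector and the second from cells in which that vector delivered PKP2, with 1 library per group and both cultures at passage 5. The vector library held 23513304 counts, with 22378 genes above 0, and the PKP2 library held 20319137 counts, with 21830 genes above 0. Genes of the mitochondrial genome took 8.07% of the counts in the vector library and 7.94% in the PKP2 library. With 1 library per group no difference given here has a replicate check and no test across samples exists, so genes are described by the size of their ratio. Ratios are the PKP2 library over the vector library on the log2 scale, and the 95% intervals of single genes cover counting error only.

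The comparison addressed which genes lie downstream of PKP2. PKP2 encodes plakophilin 2, an armadillo-repeat protein of desmosomes that ties desmosomal cadherins to desmoplakin. PKP2 (ENSG00000057294) itself had 181 counts in the vector library and 1330 in the PKP2 library, or 7.63 and 66.0 CPM, counts scaled to library size. It was 8.66-fold higher in the PKP2 library (interval 7.41 to 10.2), a log2 ratio of 3.11, in the direction of the labels.

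Beside PKP2, ADNP, LIMS1, RHOQ and BCL2L11 were over 5-fold higher in the PKP2 library, and TRIM56, DIRAS1, GJA5 and MSRB3 were over 6-fold lower. Ribosomal protein genes and nuclear genes of the respiratory chain were lower as groups, by small amounts in most members. The ATF4 and amino acid response list had a lower median, with 19 of 26 members below 0 and 7 above. Members at least 2-fold lower numbered 5, or 2 after a correction for GC content. The other desmosome genes went both ways, with the plakins DSP, EVPL and PPL lower and the cadherin DSC2 higher. CTNNB1, which encodes beta-catenin, had a ratio of -0.01 (interval -0.08 to 0.05), while EGFR and LIG4 had ratios of 0.58 and 0.57. Most genes differed little: 92.9% of the 15991 genes with a mean of at least 10 counts lay within 2-fold.

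Of these 15991 genes, 395 were at least 2-fold higher in the PKP2 library and 737 at least 2-fold lower, and with 5 CPM added to both libraries, which shrinks the ratios of low genes, 106 were higher and 81 lower. The higher genes thus made up 34.9% of the genes past 2-fold, and 56.7% with 5 CPM added. The counting interval lay wholly beyond 2-fold for 145 of the higher and 188 of the lower genes. Among the 11637 genes with a mean of at least 100 counts, 161 were at least 2-fold higher and 209 lower, and among the 4845 with a mean of at least 1000 counts, 50 were higher and 41 lower. In simulated libraries of this depth, counting error alone put 56 of 15795 unchanged genes at least 2-fold higher and 80 at least 2-fold lower.

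**Figure D1:**
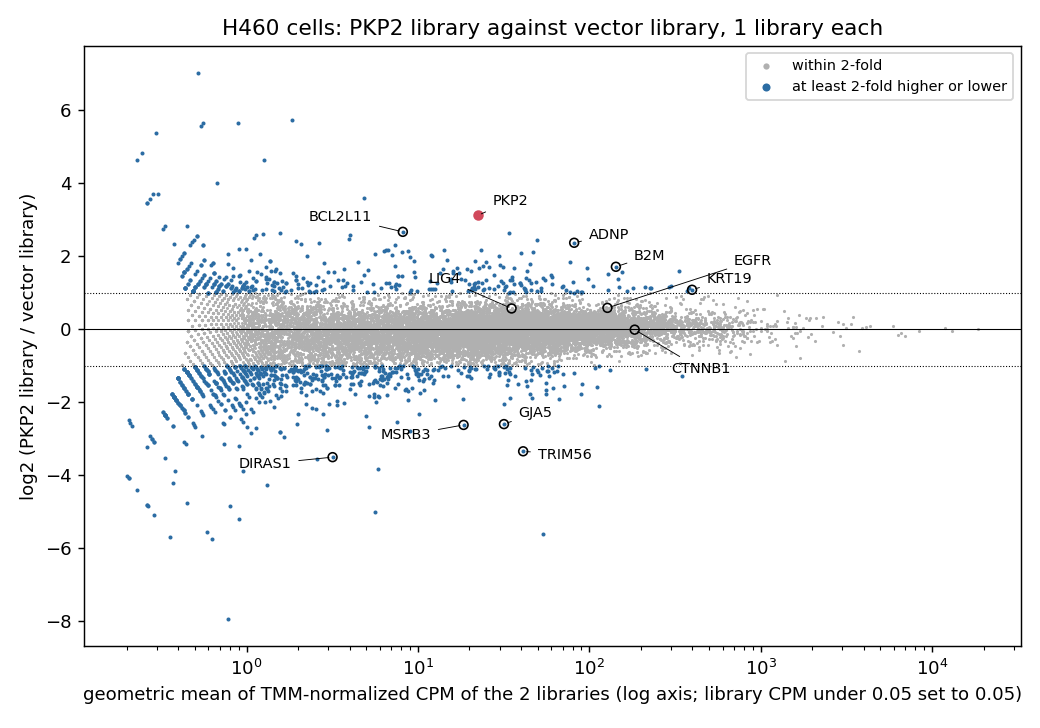
Log2 ratio of the PKP2 library over the vector library (y axis) against the geometric mean of the TMM-normalized CPM of both libraries (x axis, log scale), for the 15991 genes with a mean of at least 10 counts. Each point is a gene, blue points are at least 2-fold higher or lower (dotted lines), and the red point is PKP2, at 3.11.

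Among the 12 genes with the highest ratios, ranked with 1 CPM added, were several with many counts in the PKP2 library. ADNP (ENSG00000101126), a zinc finger and homeobox protein of chromatin, went from 854 counts in the vector library to 3731, a ratio of 2.36 (interval 2.26 to 2.47). LIMS1 (ENSG00000169756), the adaptor PINCH1 that binds integrin-linked kinase at focal adhesions, went from 506 to 2322, a ratio of 2.43, and RHOQ (ENSG00000119729), the small GTPase TC10, from 323 to 1708, a ratio of 2.64. These genes share 28.2% (LIMS1) and 27.1% (RHOQ) of their 31-base stretches with another gene, so their counts are less certain than that of ADNP, which shares 1.05%. BCL2L11 (ENSG00000153094), the pro-apoptotic protein BIM, had 77 and 414 counts, a ratio of 2.66 (interval 2.31 to 3.03). RIMBP3B (ENSG00000274600) had 0 and 119 counts, 46.7-fold higher against a floor of 3 counts (interval from 37.4-fold upward), but it shares 99.0% of its 31-base stretches with other genes.

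Among the 12 genes with the lowest ratios, TRIM56 (ENSG00000169871), an E3 ubiquitin ligase of antiviral signalling, went from 3110 counts in the vector library to 260, a ratio of -3.34 (interval -3.53 to -3.16). DIRAS1 (ENSG00000176490), a Ras-family GTPase, had 254 and 19 counts, a ratio of -3.50, and GJA5 (ENSG00000265107), the gap junction protein connexin 40, 1857 and 260, a ratio of -2.60. MSRB3 (ENSG00000174099), a methionine sulfoxide reductase, had 1088 and 150 counts, a ratio of -2.62 (interval -2.88 to -2.37), and FAM229A (ENSG00000225828), which shares 44.0% of its 31-base stretches with another gene, had 209 and 15, a ratio of -3.56. EIF2S3B (ENSG00000180574), a near copy of the translation initiation factor gene EIF2S3, had 757 and 20 counts, a ratio of -5.01, and shares 36.5%. The pseudogene RPL32P29 (ENSG00000244270) had 130 and 3 counts, a ratio of -5.20 (interval -7.50 to -3.62), and shares all of its 31-base stretches with other genes.

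Of these 24 genes at both ends, 12 overlap exons of another gene in the files on the same strand, and 12 share at least 50% of their 31-base stretches with another gene. ENSG00000255508, which has no symbol here, went from 8877 counts to 154, a ratio of -5.61, while EEF1G, the overlapping gene of a translation elongation factor subunit, went from 4595 to 11691, a ratio of 1.58. Summed with TUT1, which also overlaps, the group had 13572 and 12048 counts, a ratio of 0.06. ENSG00000198211 had 190 and 0 counts, 53.8-fold lower against the floor of 3 counts (interval from 43.3-fold upward). It overlaps TUBB3, which encodes a neuronal beta-tubulin and went from 463 to 1665 counts. The other such genes were PPAN-P2RY11 (166 and 0 counts), ENSG00000258529 (288 and 1), ENSG00000100101 (521 and 31) and RPL32P29 on the lower side. On the higher side they were ENSG00000256500 (6 and 269), ARPIN-AP3S2 (33 and 339), ISY1-RAB43 (0 and 126), ENSG00000260108 (3 and 126), ENSG00000273333 (1 and 109) and ENSG00000228470 (6 and 126). EEF1G, TUT1 and TUBB3 were looked up after their neighbours' values were seen. Counts are less certain also for genes named from lists in what follows that share at least 20% of their 31-base stretches with another gene: XRCC3 (71.5%), RAD54B (57.6%), MT-CO2 (50.5%), NDUFA1 (42.3%), DUSP6 (38.5%), ANKRD37 (33.5%), FTL (32.9%), TGFB2 (25.9%), RPS28 (25.8%), BCL2L2 (22.1%), CFLAR (20.7%), COX6A1 (20.5%) and RNF43 (20.5%). MT-ND4L, MMP2, IFIT2 and RPS29 share less but overlap another gene on the same strand.

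Across the 11610 well-counted genes with a known transcript sequence, the ratio went down with GC content (Spearman's rho -0.61 across genes, which are not independent replicates). The 1161 genes with the lowest GC content had a median ratio of 0.25 and the 1161 with the highest a median of -0.47. This trend is of the same size as the ratios of the gene groups, so medians relative to the 100 genes nearest in GC content and transcript length, a comparison chosen after the data were seen, are given beside groups outside the middle 95% of random lists by either measure, and beside homologous recombination. Where a correction for GC content alone, also chosen after the data were seen, turned the sign of a median or altered how many members were at least 2-fold higher or lower, the GC-corrected value is given too. Each group's percentile is among 10000 random lists of its size matched on mean expression, describes these libraries and is no p-value. Ratios of single genes, those of EGFR and LIG4 included, are given without a GC correction, so their counting intervals do not cover this trend.

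**Figure D2:**
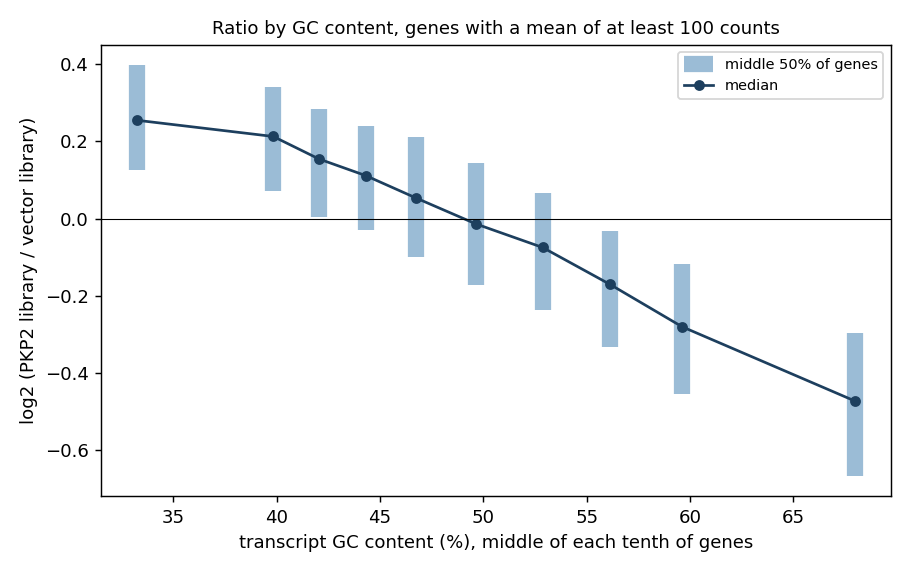
Median log2 ratio of the PKP2 library over the vector library (points) and the middle 50% of genes (bars) in 10 groups of 1161 genes by transcript GC content, for the 11610 genes with a mean of at least 100 counts and a known transcript. The median goes from 0.25 in the group of lowest GC content to -0.47 in the highest.

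Ribosomal protein genes were lower in the PKP2 library in 49 of 55 members, with a median ratio of -0.27 (interval over members -0.35 to -0.19), under all 10000 random lists. No member was 2-fold lower, and the lowest were RPS28 (-0.99), RPL13 (-0.65), RPS29 (-0.64) and RPS19 (-0.63). Nuclear genes of the respiratory chain were lower in 30 of 36 members, with a median of -0.28 (interval -0.40 to -0.16), again under all random lists and with none at 2-fold; COX8A (-0.86), COX6A1 (-0.64), NDUFA1 (-0.58) and COX5B (-0.56) were the lowest. Relative to genes nearest in GC content and length the medians were -0.16 and -0.24. The 13 mitochondrially encoded protein genes, which act in the same chain, had a median of 0.02 (-0.082 with the GC correction and 0.17 with a correction for length), from MT-CO2 at -0.10 to MT-ND4L at 0.20. MT-CO2 shares 50.5% of its 31-base stretches with other genes and MT-ND4L overlaps MT-ND4. Ribosome biogenesis genes had a median of -0.04 with all 29 within 2-fold, BOP1 (-0.53) being the farthest from 0.

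The ATF4 and amino acid response list had a median ratio of -0.24 (interval -0.50 to -0.06; percentile 0.03), and -0.13 relative to genes nearest in GC content and length. Of 26 members, 5 were at least 2-fold lower, none higher and 21 within 2-fold, and after a correction for GC content 2 were at least 2-fold lower. Ratios were below 0 in 19 members and above 0 in 7. Among the members near 0 were ASNS (-0.06), PSAT1 (0.005) and DDIT3 (0.03), and STC2 (0.48) and SLC7A11 (0.55) were higher. All of these but SLC7A11 were looked up after the values were seen. NUPR1, a stress-induced chromatin protein, was the lowest at -2.75 (182 and 23 counts), followed by CHAC1, which degrades glutathione, and ALDH1L2, a mitochondrial folate enzyme, both at -1.30, and GDF15, a stress-induced cytokine, at -1.20 (1162 and 428 counts). Hypoxia and glycolysis genes had a median of -0.16 (percentile 0.33) with 2 of 32 at least 2-fold lower. These were ANKRD37 (-1.48, with only 23 and 7 counts) and the peptide hormone gene ADM (-1.43). Relative to the nearest genes the median of hypoxia and glycolysis genes was -0.09 (interval -0.28 to 0.07; percentile 0.75). After a correction for GC content alone that list's median was -0.038 (interval -0.24 to 0.08; percentile 8.76), among the random lists. Endoplasmic reticulum chaperones had a median of 0.16 (0.058 GC-corrected), with SDF2L1 (-1.05) lower and the other 18 within 2-fold, and none at 2-fold after the GC correction. All 14 heat-shock genes were within 2-fold (median 0.06; -0.068 GC-corrected), HSPB1 (-0.55) being the farthest from 0, and so were all 30 NRF2 target genes (median -0.04; 0.032 GC-corrected), where the ferritin light chain gene FTL was at -0.59 and the cystine transporter gene SLC7A11 at 0.55.

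NF-kB and inflammatory genes had a median ratio of -0.22 (interval -0.59 to -0.06; percentile 0.66), and -0.19 (interval -0.42 to 0.04) relative to genes nearest in GC content and length. The cytokine IL32 (-2.42, with only 44 and 7 counts) and complement C3 (-1.55; 2876 and 835 counts) were at least 2-fold lower. The other 22 were within 2-fold, including the neutrophil chemokines CXCL8 (0.89) and CXCL1 (0.78), which were higher. Interferon-stimulated genes had a median of 0.06 (-0.013 GC-corrected). Of these, OASL (-1.54, with only 48 and 14 counts), IFIT2 (-1.17) and ISG15 (-1.05) were at least 2-fold lower and 31 within. After the GC correction 2 were lower. Of 28 p53 target genes (median -0.10, and -0.10 at percentile 1.35 relative to the nearest genes), BBC3 (-1.42), which encodes the pro-apoptotic protein PUMA, and GDF15 were at least 2-fold lower and 26 within, with none at 2-fold after a correction for GC content. The apoptosis regulators split, with BCL2L11 and CFLAR (1.03), an inhibitor of caspase 8, higher, BBC3 and BCL2L2 (-1.66) lower and 17 within 2-fold (median 0.13; 0.056 GC-corrected). After the GC correction 1 was higher and 1 lower. BCL2L2 overlaps a read-through gene, and summed over that group its ratio was -0.49. The other genes of the group had 2988 and 1928 counts and went the same way, at -0.40. They hold most of the summed counts, so the sum cannot tell how reads were assigned.

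In the desmosome list 2 of 10 measured genes were at least 2-fold lower and none higher (median -0.04; percentile 35.7), and with the GC correction 1 was lower and the median was 0.048. EVPL, which encodes envoplakin, was at -1.26 (1090 and 387 counts), DSP, desmoplakin, at -1.14 with only 52 and 20 counts, PPL, periplakin, at -0.99 and DSC2, desmocollin 2, at 0.85 (607 and 927 counts). Epithelial junction and keratin genes had a median of -0.04 (0.045 GC-corrected): KRT19 (1.08; 6501 and 11645 counts) and OCLN (1.12; 13 and 24 counts) were at least 2-fold higher, CLDN7 (-1.50; 50 and 15 counts) lower and 11 within 2-fold, with 1 higher and 1 lower after the GC correction. Among mesenchymal genes (median 0.02) MMP2 (-2.83), THBS1 (-1.81) and the receptor tyrosine kinase AXL (-1.23) were at least 2-fold lower and 14 within, although MMP2 and THBS1 had under 100 counts. Of 15 beta-catenin/TCF target genes (median -0.30, interval -0.86 to 0.11; percentile 5.08), the Wnt feedback inhibitors RNF43 (-2.00; 269 and 57 counts) and AXIN2 (-1.40; 28 and 9 counts) were at least 2-fold lower and 13 within. RNF43 overlaps SUPT4H1, looked up after the values were seen, on the same strand, and summed over both genes the ratio was -0.29. SUPT4H1 alone had 1243 and 990 counts, a ratio of -0.09, within counting error. It holds most of the summed counts, so the sum cannot tell whether reads moved between them. Relative to the nearest genes the list's median was -0.23 (interval -0.80 to 0.23; percentile 2.09).

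All 14 genes of the EGFR family and its ligands were within 2-fold, with a median of 0.06, and of 0.20 (interval -0.14 to 0.54; percentile 99.0) relative to the nearest genes. EGFR (ENSG00000146648) had 2476 and 3146 counts, a ratio of 0.58 (interval 0.51 to 0.66). The ligand genes EREG (0.85; 17 and 26 counts; interval -0.09 to 1.82) and TGFA (-0.71; 25 and 13 counts; interval -1.80 to 0.31) lay on opposite sides of 0. Both have few counts and intervals that take in 0. Of 23 ERK-output genes (median 0.05), the receptor EPHA4 (1.34), the ERK phosphatase DUSP6 (1.14; 667 and 1244 counts; 38.5% shared) and IER2 (1.08) were at least 2-fold higher and the feedback inhibitor SPRY1 (-1.49; 43 and 13 counts) lower, with 19 within, and 4 were higher and 1 lower after the GC correction. Focal adhesion and integrin genes had a median of -0.00 (0.16 GC-corrected) with ITGB4 (1.13) higher and 25 within 2-fold, among them ITGA6 (0.83) and ITGA2 (-0.80). ITGB4 had only 7 and 13 counts, and its interval of -0.30 to 2.70 takes in 0. Relative to the nearest genes their median was 0.17 (interval 0.01 to 0.33; percentile 99.9), with 19 of 26 above 0. YAP/TEAD target genes had a median of 0.17 (interval -0.11 to 0.42; percentile 98.2), with AXL lower and 20 within 2-fold, including CCN2 (0.75) and NT5E (0.78), and a median of 0.25 (interval -0.07 to 0.38) relative to the nearest genes. Of 16 TGF-beta target genes (median -0.12; 0.081 GC-corrected), COL1A1 (-1.22) was lower, a call lost with the GC correction, and 15 were within 2-fold, with INHBA at 0.97 and TGFB2 at 0.93.

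In non-homologous end joining all 16 genes were within 2-fold (median -0.01). LIG4 (ENSG00000174405), the ligase of this pathway, had 687 and 863 counts, a ratio of 0.57 (interval 0.42 to 0.71), RIF1 was at 0.39 and PAXX at -0.96. Homologous recombination and Fanconi genes were also all within 2-fold but higher in 23 of 27 members, with a median of 0.14 (interval 0.06 to 0.22; percentile 96.4) and examples RAD54B (0.66), BRCA2 (0.47) and XRCC3 (-0.48). Relative to genes nearest in GC content and length that median was -0.019, and GC-corrected -0.025. All 37 DNA replication genes were within 2-fold (median 0.01), with the licensing factor CDT1 at -0.72, and of 37 mitosis genes (median 0.06; -0.044 GC-corrected, interval -0.060 to -0.012) the transcription factor FOXM1 (1.16; 1105 and 2090 counts) was higher and the rest within 2-fold. In cholesterol biosynthesis (median -0.06; 0.057 GC-corrected) the desaturase SC5D (2.01; 352 and 1202 counts) was higher, INSIG1 (-1.13), which holds back cholesterol synthesis, lower and 22 within.

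Of 20 listed replication-dependent histone genes only 9 reached the count minimum, with a median ratio of 0.29 (percentile 97.4). Among these, H2BC8 (1.31; 10 and 21 counts) was higher and the others were within 2-fold. Relative to the nearest genes their median was 0.49 (interval 0.32 to 0.62; percentile 99.7). These medians do not cover the members under the minimum. Of 23 housekeeping reference genes (median -0.01; 0.048 GC-corrected) 22 were within 2-fold, and B2M, the light chain of MHC class I, was higher at 1.71 (1879 and 5206 counts). Among markers of other cell types, 8 fibroblast markers were measured (median -0.17), of which COL3A1 (-1.31) and COL1A1 were at least 2-fold lower, PDGFRB (1.14) higher and 5 within, with 1 lower after the GC correction. Leukocyte markers had 3 measured members, with CD14 (-1.73; 90 and 23 counts) lower, and endothelial markers had 1, ESAM (-0.29). Of 3 squamous markers KRT15 (5 and 25 counts) was higher, of 2 alveolar and airway markers AGER (78 and 33 counts) was at least 2-fold lower, and of 10 neuroendocrine markers (median -0.05; 0.11 GC-corrected) NCAM1 (1.03) was higher and INSM1 (-2.35; 30 and 5 counts) lower.

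**Figure D3:**
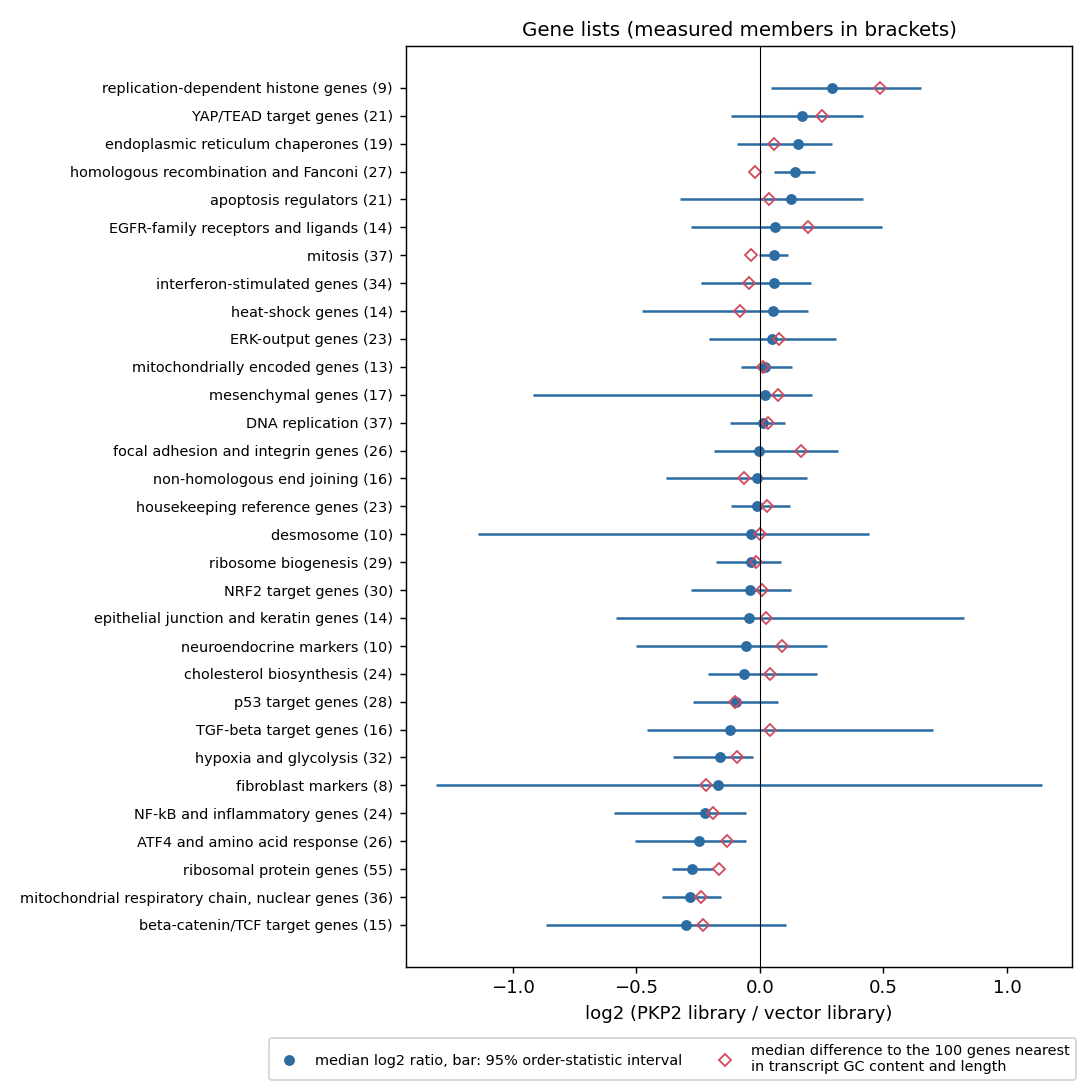
Median log2 ratio of the PKP2 library over the vector library for each gene list with at least 6 measured members (circles; bars are 95% order-statistic intervals over members) and the median difference to the 100 genes nearest in GC content and length (diamonds). Ribosomal protein genes lie at -0.27 and -0.16, and homologous recombination genes at 0.14 and -0.019.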

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

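The pseudocount of 1 CPM, DESeq2 size factors, corrections for GC content and length, and the restriction by shared sequence were chosen after the data were seen. No paired analysis was possible because each group has 1 library. PKP2 stayed higher under all alternatives run, its lowest ratio being 2.49 with 5 CPM added. The counts of genes at least 2-fold higher and lower were 231 and 393 with 0.5 CPM added, 180 and 249 with 1 CPM, 106 and 81 with 5 CPM, 1312 and 1728 with no filter on low values, 195 and 304 at a mean of at least 50 counts, and 251 and 490 among genes with less than 10% of 31-mers shared. They were 1098 and 2060 at 1.5-fold and 114 and 251 at 3-fold. With the GC correction 380 were higher and 560 lower. Of the 395 higher and 737 lower genes without it, 314 and 497 kept their call. Fewer genes entered under the stricter filter and the restriction, and added CPM shrinks ratios by construction. Plain CPM, upper-quartile scaling, centring and DESeq2 size factors kept both counts within 1.5 times and moved no list median out of its interval. The medians that left their interval did so under corrections that change ratios with GC content or length, and the cause was not tested further. Under the GC correction, GC then length, and the 100 nearest genes, homologous recombination had medians of -0.025, -0.041 and -0.019, and mitosis -0.044, -0.043 and -0.034. Ribosomal protein genes had -0.14 under length alone, -0.15 under GC then length and -0.16 against the nearest genes, and mitochondrially encoded genes -0.082 under GC alone but 0.17 under length alone. After the GC correction fewer members were at least 2-fold lower in the ATF4 (2 against 5), p53 (0 against 2), desmosome (1 against 2), interferon (2 against 3), apoptosis (1 against 2), fibroblast (1 against 2), TGF-beta (0 against 1) and chaperone (0 against 1) lists; fewer were at least 2-fold higher in the epithelial and apoptosis lists (1 against 2 in each), and more in the ERK-output list (4 against 3). Of 31 lists, 6 lay outside the middle 95% of matched random lists and 4 outside that of unmatched ones, 3 under both: ribosomal protein, respiratory chain and ATF4 genes. Of 2106 values of named genes under alternatives, 343 left the counting interval, and no gene at least 2-fold higher or lower changed direction. These were unevenly spread over the settings. Under the GC correction 67 genes left it and 85 stayed, and 74 left it under GC then length, 69 against the nearest genes and 61 with 5 CPM added. None left it under DESeq2 size factors or centring. Ratios of single genes are given here without a GC correction. Genes with few counts are limited by depth. Among genes called at least 2-fold higher or lower, OCLN, ITGB4, AXIN2, THBS1, ANKRD37, H2BC8 and KRT15 had under 30 counts in both libraries.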

Other observations

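Collagen genes had mostly lower counts in the PKP2 library. This family and 16 others were looked at after the data were seen, so they are no independent evidence. Of 26 measured collagen genes 22 had ratios below 0, with a median of -0.75 (interval over members -0.99 to -0.08), under all 10000 random lists, and 7 were at least 2-fold lower, among them COL3A1 (-1.31; 973 and 333 counts) and COL18A1 (-1.15; 175 and 67 counts). COL12A1, with more counts, was at -0.74 (5895 and 3005 counts), while COL5A2, the most abundant at 76524 and 70960 counts, was at 0.13 and the basement membrane gene COL4A6 at -0.01. COL8A1 went the other way, at 1.37 (2165 and 4737 counts). Relative to genes nearest in GC content and length the collagen median was -0.33 (interval -0.66 to 0.00, which takes in 0).

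B2M stood apart from other genes of antigen presentation. Against its ratio of 1.71, HLA-B was at 0.01 and HLA-C at 0.30, and the peptide transporter gene TAP1 was at -0.01. Mitochondrial ribosomal protein genes, 75 in all, had a median of -0.09 (percentile 1.39), less far from 0 than the cytoplasmic ones, and -0.10 relative to the nearest genes. Semaphorins and plexins had a median of -0.32 that was 0.03 relative to the nearest genes, and Rab GTPases a median of 0.13 that was 0.05.

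The tests that follow were chosen or redefined after results were seen, except the share of genes with few shared sequences. For that share the bound on shared 31-mers was raised from 1% to 10% when 31.3% of all measured genes proved to lie under 1%, before the share itself was computed. The GC content and length tests were run first on the longest transcript and again on the principal one after those values were seen, and the nearest-gene test was repeated with coding length and with the longest transcript. PKP2 overexpression and library are the same split with 1 library per group, so no biological explanation was tested for any of the 3 patterns.

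The first pattern is the lower ratios of ribosomal protein and nuclear respiratory chain genes. After correction for GC content the medians were -0.22 and -0.24, and after correction for length -0.14 and -0.21 (-0.24, -0.24, -0.17 and -0.20 with the longest transcript), all with intervals below 0 and under the 2.5th percentile. Against the 100 genes nearest in both they were -0.16 (interval -0.23 to -0.11) and -0.24 (interval -0.30 to -0.14), -0.19 and -0.24 with coding length, and -0.23 in both with the longest transcript. The nearest genes were taken without the members of both lists and of the ATF4 list, which can make the remaining difference larger. The corrected medians argue against GC content or length, each alone, as the whole cause. For both together the nearest-gene medians point the same way, within that limit. For ribosomal protein genes the median moved from -0.27 to -0.16, so GC content and length may account for part of it. RNA handling, culture state and PKP2 itself stay open.

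The second pattern is the lower ATF4 and amino acid response list. After correction for GC content its median was -0.13 (interval -0.36 to -0.06; -0.12 with the longest transcript), and against the 100 genes nearest in GC content and length it was -0.13 (interval -0.39 to -0.05; -0.17 with coding length; -0.12 with the longest transcript), which argues against GC content, alone or with length, as the whole cause, though it may account for part. After correction for length alone the median was -0.21 (interval -0.50 to -0.02), and with the longest transcript -0.18 with an interval of -0.49 to 0.00 that takes in 0, so that test by itself does not settle length, while the nearest-gene medians, which remove GC content and length together, stayed below 0. Here too the nearest genes were taken without the members of the ATF4, ribosomal protein and respiratory chain lists, which can make the remaining difference larger. Amino acid supply, which this response follows, was not analysed here.

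The third pattern is the 370 genes with a mean of at least 100 counts that differ at least 2-fold. Of these, 68.4% share less than 10% of their 31-mers with another gene, against 72.7% of other well-counted genes, and 8.38% against 5.97% share at least 50%. The 68.4% is over the 50% set beforehand, but so is the 72.7% of the other genes. Under the first bound of 1% the share was 34.3% (127 genes), below 50%, against 31.3% of all measured genes. The comparison with 50% thus follows the bound and the share among genes at large, so it cannot decide whether shared reads are the cause. The shares show only that most of the 370 genes share few stretches under the raised bound, slightly less often than other genes. For the 74 that overlap another gene on the same strand, 20% of the 370 against 11.2% of the others, the assignment of reads between them stays open: in the 47 of 69 overlapping groups whose other genes, summed, differed beyond counting error, these went the opposite way in 42.6% (interval 28.3% to 57.8%). After correction for GC content 65.4% still differ at least 2-fold (65.1% with the longest transcript), so the median trend with GC content does not by itself make up these differences. That trend runs only from 0.25 in the group of lowest GC content to -0.47 in the highest. Genes far past 2-fold therefore keep their call whatever the cause, and the share cannot settle GC content further. Variation between cultures stays open for all 370 genes.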
